A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

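The samples were cultures of Saccharomyces cerevisiae BY4741, a laboratory strain of budding yeast, sampled before and after Congo Red was added at 30 µg/ml. Congo Red is a dye that binds chitin and disturbs the assembly of the cell wall. Per the labels' protocols, cells grew at 24 °C in rich medium with glucose, were sampled at 0, 30, 60, 120, 180 and 240 min, and the volume collected was adjusted to the size of the cells. Each of the 12 groups, made of 2 assays and 6 times, held 3 replicate arrays, which gave 36 arrays. Per the labels' protocols, mRNA abundance was measured on cDNA made with an oligo-dT primer and labelled with 33P-dCTP. Nascent transcription was measured by genomic run-on, in which permeabilised cells extend the transcripts they had begun while 33P-UTP is present. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical.

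Each array file holds 1 intensity per spot as the authors deposited it, with no background column, flag or gene name. The 6144 spots lie in 384 blocks, 16 by 24, with 16 printing positions in each. No pair among the 630 pairs of arrays held identical values. The authors also deposited a table for the whole series with 1 signal per spot, time and measure, in which the replicates had been combined; all of its 12 columns were used. Per the series' design text, synthesis rate was the nascent transcription rate normalised to cell volume, with factors of 1 until 60 min and of 1.17, 1.44 and 1.65 at 120, 180 and 240 min. Scanner, image software, background treatment and the scaling of that table are not given in the sources used here. The table held a value in all columns for 4468 spots and in at least 1 column for 4918.

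The files do not pair spots with genes. None of the spot identifiers matched the 6477 genes of the reference table (0 matches), so no gene is named. For the same reason the 35 gene lists fixed before the data were examined, the genes always to be named and the checks of strain markers were not run. The design had assumed gene names and the averaging of spots of 1 gene, and here each spot was tested by itself.

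Intensities of 0 were set to missing and the others were taken to log2 with no pseudocount. A spot entered the fit of an assay when at least 2 of the 3 replicates of every group were above 0, which left 4882 spots for mRNA abundance and 5113 for nascent transcription, and 4805 in both. Arrays were quantile normalised within an assay with limma 3.58.1 in R 4.3.3. A linear model with time as a factor was fitted to the 18 arrays of an assay, and each later time was tested against 0 min with limma's moderated test. Late was tested against early as 240 min against 30 min, and any change over the course with the moderated F-test. All p-values were adjusted with the Benjamini-Hochberg method and the threshold was 0.05. The difference between the change in mRNA and the change in nascent transcription was tested as an interaction over all 36 arrays with array weights estimated per assay. These tests were fixed before the data were examined. Quantile normalisation removes any change common to all spots, so changes are relative to the typical spot of the array. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

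The labels state only that each sample holds replicates 1 to 3. Which array is which replicate was taken from the numbering of the array files of a sample, and all results on pairing, blocks and single arrays rest on that reading. It was checked whether arrays of the same number deviated together from their group means. The 3 deviations at a time add up to 0 for each spot, so pairs with different numbers lean below 0 when same-numbered pairs correlate. On the mRNA arrays pairs with different numbers had a median of -0.413, which is thus no separate support. All 45 pairs of mRNA arrays with the same number correlated between 0.615 and 0.846 across spots. The numbers therefore paired the mRNA arrays, on the basis of the data and not of the labels, and a fit with the replicate number as a block is given beside the mRNA results. Its median residual SD was 0.248 (log2), against 0.439 without the block. On the nascent arrays 13 of the 45 pairs were at or below 0.1, so the block was treated there as an alternative.

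The rule for named items took, for each assay and time, those with the largest change past the threshold whose replicates at that time all lay on 1 side of all replicates at 0 min. Because no gene could be named, it was limited to the 2 largest rises and the 2 largest falls in mRNA at 240 min, and the limit was set after the data had been seen. Sets of spots that changed in 1 assay were followed in the other with limma's camera at a preset correlation of 0.01, camera with an estimated correlation, and the rotation test fry, adjusted over 200 tests. These set tests, and the simulations of unchanged groups against the real 0 min arrays, were chosen after the data had been seen.

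The fits were tested on simulated data made from the spread of these arrays with 100 spots changed 2-fold and 100 changed 4-fold. For mRNA at 240 min, 24 of the 2-fold and 72 of the 4-fold changes were recovered with 0 unchanged spots called among 4882. With the replicate block 66 and 94 were recovered and 10 unchanged spots were called. For nascent transcription at 240 min, 49 and 92 were recovered with 6 unchanged spots called among 5113. The interaction recovered 103 of 189 simulated 4-fold differences, or 54.5%, with 0 unchanged spots called among 4805. The totals of 4882, 5113 and 4805 count all spots tested, the changed ones included. The simulated arrays held differences between replicate numbers and noise drawn independently for each spot, but no drift of printing positions. The counts of unchanged spots called may therefore not carry over to the real arrays. The number of arrays limits the precision.

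Alternatives tried were scaling to a common median, cyclic loess, leaving out the dimmest 20% of spots, the replicate block, a trended and robust variance prior, only the 6 arrays compared, no array weights, the values of the authors' table, and leaving out each replicate in turn. Others were added after the data had been seen. These were centring each printing position on its median on each array, the same with the replicate block, leaving out printing position 3, leaving out the spots blank in the authors' table, taking the authors' ratios less their median over spots, and leaving out the 0 min arrays when late was compared with early.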

Results

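The data set followed yeast in Congo Red for 240 min and measured, at the same 6 times, how much of each mRNA was present and how much was being transcribed. Each assay had 18 arrays, 3 at each time, with 6144 spots per array. Total intensity ran from 387130 to 1661000 on the mRNA arrays and from 512220 to 1880500 on the nascent arrays. Between 14.9% and 18.2% of the spots of an array were listed at 0. Across spots, replicate arrays of a group correlated between 0.874 and 0.954 on the log2 scale. The time course was compared with 0 min at each time, late with early, and mRNA with nascent transcription. The series holds no sample without the dye after 0 min. Effects of the dye therefore cannot be told apart from those of time in culture in any of these comparisons.

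The first comparison asked which transcripts changed in abundance between 0 min and the later times in Congo Red. At 240 min the mRNA of 67 spots had risen and that of 14 had fallen, of 4882 tested (limma, adjusted p under 0.05). The risers had a median log2 change of 1.53, which is 2.89-fold, and the fallers one of -1.03, which is 2.04-fold. More spots passed from 120 min on than before. At 30 min 0 spots passed and 122 lay under an unadjusted p of 0.05, where chance gives 244. The fit with the replicate block put 411 spots under it, so the 122 do not show a lack of change. At 60 min 5 spots had risen and 0 had fallen, at 120 min 34 had risen and 0 had fallen, and at 180 min 68 had risen and 18 had fallen. The median fold of the risers was 3.24 at 120 min and 2.97 at 180 min. With the replicate number as a block, 11 rose and 0 fell at 30 min, 75 rose and 24 fell at 60 min, 214 and 106 at 120 min, 385 and 285 at 180 min, and 359 and 280 at 240 min. The F-test over the course passed 27 spots, and 298 with the block.

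**Figure D1:**
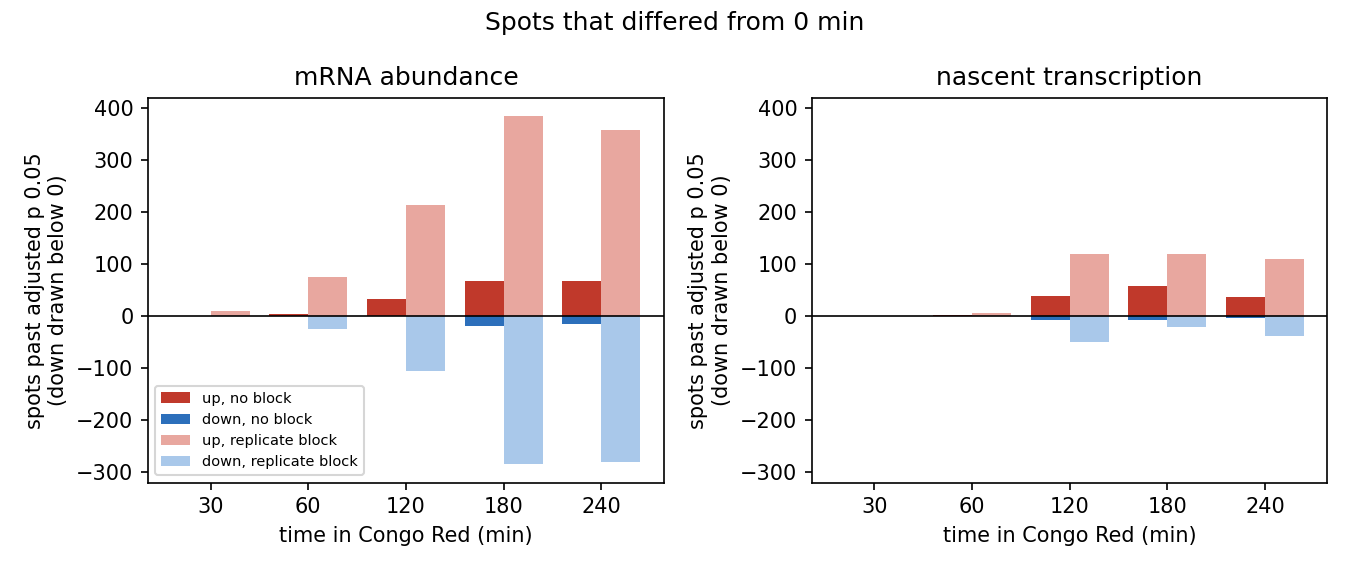
Number of spots whose mRNA abundance (left) or nascent transcription (right) passed an adjusted p of 0.05 (limma) at each time in Congo Red (min) against 0 min. Spots that rose are drawn above 0 and spots that fell below 0, dark without and light with the replicate number as a block. Without the block the mRNA risers went from 0 at 30 min to 67 at 240 min and the nascent risers from 1 to 37. With it they went from 11 to 359 and from 1 to 110.

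All 81 spots called in mRNA at 240 min and all 86 called at 180 min were also called with the block. The balance of rises and falls depended on the block and on the scaling. Rises made up 82.7% of the calls at 240 min without the block and 56.2% with it. At 180 min these shares were 79.1% and 57.5%. At 240 min 83 rose and 44 fell when arrays were scaled to a common median, and 81 and 34 when each printing position was centred. At 180 min these splits were 84 and 43, and 64 and 37. At 120 min the split was 47 and 6 with cyclic loess and 29 and 4 after centring. Almost no mRNA calls remained when only the 6 arrays compared were fitted, a fit that rests on fewer arrays. Its counts are given with the other processing alternatives below. Single arrays moved the counts. The 81 spots at 240 min became 40 without replicate 2 at 0 min, 39 without replicate 1 at 240 min and 31 without replicate 2 at 240 min. The 86 at 180 min became 37 and 56 without replicates 2 and 3 at 0 min, and 43 and 51 without replicates 1 and 2 at 180 min. The 34 at 120 min became 20 and 18 without replicates 2 and 3 at 0 min, and 21 and 16 without replicates 1 and 2 at 120 min. The 5 at 60 min became 2 and 8 without replicates 2 and 3 at 0 min, and 3 without replicate 3 at 60 min. The 0 at 30 min became 1 without replicate 1 at 0 min, and the 27 of the F-test became 16 without replicate 2 at 0 min.

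The same spots were often called at successive times. Among 4591 spots with a value on all 18 mRNA arrays, 71 rose at 180 min and 77 at 240 min, and 60 rose at both, where independent lists would share 1.19. Of 18 that fell at 180 min and 15 that fell at 240 min, 10 fell at both, where 0.0588 would be shared. All 35 spots that had risen at 120 min in this set were up at 180 min too. Across spots the changes at 180 and 240 min correlated at 0.892, with a covariance of 0.264. Unchanged groups simulated against the same 0 min arrays gave 0.492 and a covariance of 0.174, and 0 spots called at both times. That simulation drew the arrays independently, although the numbers paired them. With the differences between numbers kept in the simulated arrays the covariance was 0.0448. For 60 and 120 min the covariance was 0.163, against 0.172 in the independent simulation and 0.0458 in the paired one. The 3 control arrays could not be split with at least 2 in each part, so some of the excess over independent lists may come from the shared controls. The simulated groups were set against those same controls.

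The files do not pair spots with genes, so the largest changes are given by the spot's place on the array. Spot R7 - C16 : 1 had the largest rise in mRNA at 240 min among those that met the naming rule. Its log2 intensity was 1.88 ± 1.06 (SD, n = 3) at 0 min and 5.74 ± 0.51 (SD, n = 3) at 240 min, a log2 change of 3.86 ± 0.72 (SE) (limma adjusted p = 0.0127). It stood at 1.98 at 120 min (limma adjusted p = 0.373) and at 3.29 at 180 min (limma adjusted p = 0.0285). With the replicate block the limma adjusted p was 0.00207 at 120 min and 1.36e-05 at 240 min. The adjusted p at 240 min became 0.0557 and 0.0551 without replicates 1 and 2 at 0 min, and 0.0521 without replicate 2 at 240 min. Its nascent signal differed from 0 min by 1.12 at 240 min (limma adjusted p = 0.16, and 0.0393 with the block). Without nascent replicate 1 at 240 min that change was 1.53 (adjusted p = 0.0287 in limma). The ratio in the authors' table was -0.10, or 0.71 relative to the median spot of that table.

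Spot R14 - C17 : 8 had a log2 change in mRNA of 3.63 ± 0.84 (SE) at 240 min (limma adjusted p = 0.0424). Its 0 min arrays spread by an SD of 2.62 around a log2 intensity of 0.38, so the size of the rise is poorly known, and the authors' table gave 1.64, or 2.27 relative to its median spot. Without replicate 3 at 0 min the change was 2.10 (limma adjusted p = 0.00316). The adjusted p became 0.0585 with arrays scaled to a common median, and 0.129, 0.154 and 0.0852 without replicates 1, 2 and 3 at 240 min. Its nascent signal was 0.02 from 0 min (adjusted p = 0.984 in limma). Spot R2 - C1 : 7 had the largest fall in mRNA at 240 min among those that met the naming rule, with a log2 change of -3.17 ± 0.52 (SE) (limma adjusted p = 0.00566), and its adjusted p stayed under 0.05 in the 9 alternatives that covered it. Spot R11 - C5 : 12 had a change of -2.29 ± 0.47 (SE) (limma adjusted p = 0.0255). Its adjusted p lay between 0.0536 and 0.113 when any 1 of the 6 arrays compared was left out, and its nascent signal was 0.39 from 0 min (limma adjusted p = 0.91). All of these spots were dim, at percentiles 18.3, 10.7, 5.18 and 1.04 of mean mRNA signal in the order given. No background value was present to subtract, so the sizes of these changes are rough. The authors' table gave no mRNA ratio at 240 min for R2 - C1 : 7 or R11 - C5 : 12.

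The second comparison asked which transcripts were made faster or slower. Nascent transcription rose at 37 spots and fell at 4 at 240 min, of 5113 tested (limma, adjusted p under 0.05). The risers had a median log2 change of 1.42, or 2.67-fold. At 30 min 1 spot had risen and 0 had fallen, and 109 lay under an unadjusted p of 0.05 where chance gives 256. At 60 min 2 had risen and 0 had fallen, and 223 lay under an unadjusted p of 0.05. The fit with the replicate block, only an alternative here, put 193 spots under it at 30 min and 367 at 60 min. The 109 and the 223 therefore do not show a lack of change. At 120 min 39 had risen by a median of 2.22-fold and 8 had fallen by a median of 2.50-fold. At 180 min 58 had risen by a median of 2.33-fold and 7 had fallen by a median of 1.80-fold. The F-test over the course passed 33 spots. Of the 8 spots that fell at 120 min, 4 lay at printing position 3, which held 334 of the spots tested and drifted between arrays.

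**Figure D2:**
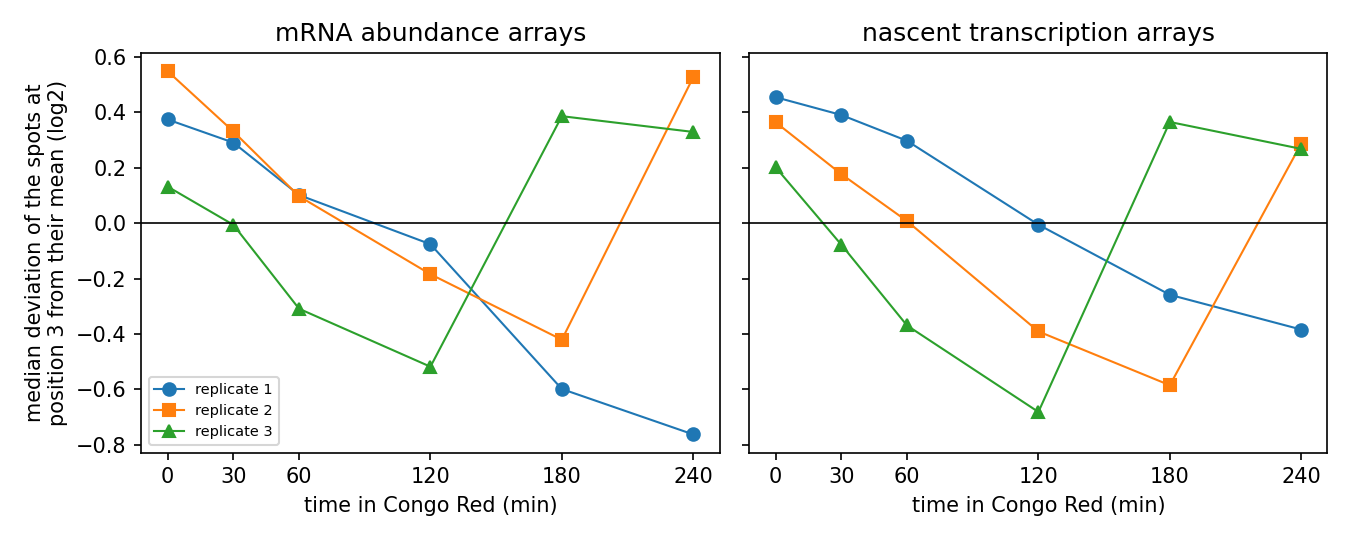
Median deviation (log2) of the spots at printing position 3 from their mean over the arrays of the assay, against time in Congo Red (min), for each replicate of the mRNA arrays (left) and the nascent arrays (right). On the mRNA arrays replicates 1, 2 and 3 stood at 0.37, 0.55 and 0.13 at 0 min and at -0.76, 0.53 and 0.33 at 240 min. On the nascent arrays they stood at 0.45, 0.36 and 0.20, and at -0.38, 0.29 and 0.27.

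Single arrays also moved the nascent counts. The 41 spots at 240 min became 146 without replicate 1 at 240 min, 22 and 12 without replicates 2 and 3 at 240 min, and 16 without replicate 2 at 0 min. Centring each printing position gave 88, of which 74 rose and 14 fell. The 65 spots at 180 min became 33 and 25 without replicates 1 and 2 at 0 min, and 27, 21 and 43 without replicates 1, 2 and 3 at 180 min. The 47 at 120 min became 18 and 21 without replicates 1 and 2 at 0 min, and 29, 19 and 18 without replicates 1, 2 and 3 at 120 min. The 2 at 60 min became 1 without replicate 1 or 2 at 0 min or replicate 2 or 3 at 60 min, and the 1 at 30 min became 2 without replicate 3 at 0 min. The 33 of the F-test became 11 without replicate 2 at 0 min, 20 without replicate 3 at 30 min or replicate 2 at 60 min, 21 without replicate 2 at 180 min, and 73 without replicate 1 at 240 min.

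Nascent changes too were shared between late times. Among 5003 spots with a value on all 18 nascent arrays, 61 rose at 180 min and 37 at 240 min, and 33 rose at both, where independent lists would share 0.451 and the simulation of unchanged groups gave 0.05. Across spots the changes at these times correlated at 0.838 with a covariance of 0.157, and the simulation gave 0.495 and 0.0624. As in the mRNA arrays, the 0 min arrays could not be split, so part of the excess over independent lists may come from the shared controls.

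Late times were compared directly with early ones, in the fit to all 18 arrays of an assay. Between 30 and 240 min the mRNA of 5 spots rose and of 0 fell (limma), with a median log2 change of 1.42, and 232 spots lay under an unadjusted p of 0.05. With the replicate block 56 rose and 21 fell. When the 0 min arrays were left out of the normalisation and the fit, 2 rose and 0 fell. The 5 spots became 3, 2 and 3 without replicates 1, 2 and 3 at 30 min, and 2 without replicate 1 or 2 at 240 min. Nascent transcription rose at 9 spots and fell at 4 over the same interval, by medians of 1.26 and -1.28. The split was 9 and 2 with arrays scaled to a common median, and 5 and 1 with the 0 min arrays left out. These 13 spots became 4, 7 and 5 without replicates 1, 2 and 3 at 30 min, and 43 and 4 without replicates 1 and 3 at 240 min.

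The third comparison set mRNA against its transcription. Spots whose mRNA had changed tended to have a nascent signal on the same side of 0 min. Of the 67 spots with raised mRNA at 240 min, 64 had a nascent change above 0 at that time and 14 were themselves called up. Their median nascent log2 change was 0.20 at 30 min, 0.35 at 60 min, 0.73 at 120 min, 0.58 at 180 min and 0.68 at 240 min. At 240 min camera gave an adjusted p of 1.48e-27 with the preset correlation and adjusted p = 0.015 with an estimated correlation, and fry gave 0.0013 (limma). At 30 min the preset correlation gave 8.67e-06, the estimated correlation adjusted p = 0.239 and fry 0.314. For 60, 120 and 180 min the estimated correlation gave adjusted p = 0.0367, 0.0217 and 0.0176 (camera). The 34 spots whose mRNA had risen by 120 min had median nascent changes of 0.36 at 30 min and 1.07 at 120 min, and all 34 were above 0 at 120 min.

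The 13 spots with lowered mRNA at 240 min that were also measured in the nascent assay had median nascent changes of -0.35 at 60 min, -0.72 at 120 min and -0.44 at 240 min, with 11 of 13 below 0 at 240 min and 0 called. Camera gave an adjusted p of 0.00012 at 240 min with the preset correlation, adjusted p = 0.111 with an estimated correlation, and fry gave 0.045 (limma). With the replicate block, 358 spots with raised mRNA at 240 min had a median nascent change of 0.37, with adjusted p = 0.0106 for an estimated correlation, and 268 with lowered mRNA had one of -0.31, with adjusted p = 0.0612 (camera). In the other direction, 36 of the 39 spots with raised nascent transcription at 120 min had a value on all 18 mRNA arrays, and these had median mRNA changes of 0.35, 0.65, 1.03, 1.22 and 1.07 at 30, 60, 120, 180 and 240 min. Camera with an estimated correlation gave adjusted p = 0.00517 at 30 min and 0.00223 at 240 min. Calls in both assays overlapped in 13 rising spots at 120 min, 20 at 180 min and 14 at 240 min, where independent lists would share 0.269, 0.807 and 0.502. At these times 0 spots were called in opposite directions. Few falls were called, 0, 16 and 13 in mRNA and 8, 7 and 4 in nascent transcription, so that 0 carries little weight. With the block the overlaps were 47, 61 and 48, where independent lists would share 5.03, 9.21 and 7.82.

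**Figure D3:**
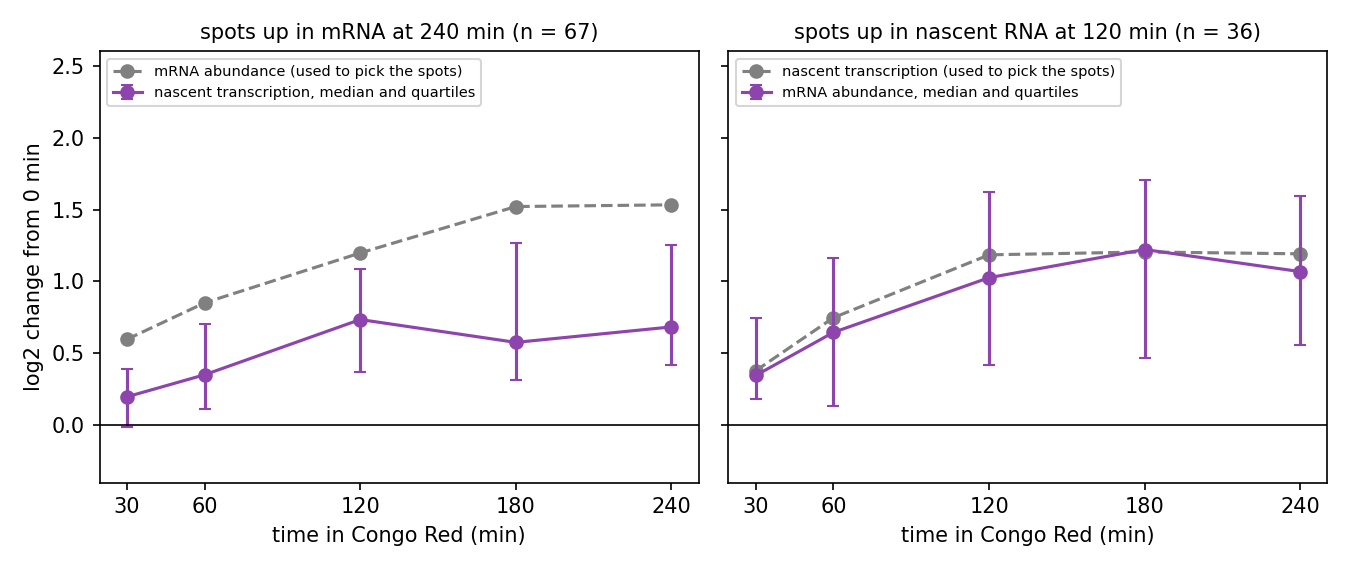
Log2 change from 0 min against time in Congo Red (min) for 67 spots called up in mRNA at 240 min (left) and for the 36 spots called up in nascent transcription at 120 min that had a value on all mRNA arrays (right). Dashed grey lines are medians in the assay used to pick the spots, and purple lines are medians in the other assay with bars from the lower to the upper quartile over spots. The nascent median of the mRNA risers went from 0.20 at 30 min to 0.68 at 240 min, and the mRNA median of the nascent risers from 0.35 to 1.07.

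Across 4805 spots the change in mRNA and the change in nascent transcription correlated at Pearson's r of 0.16, 0.41, 0.58, 0.50 and 0.46 at 30, 60, 120, 180 and 240 min, and at Spearman's rho of 0.24, 0.41, 0.54, 0.47 and 0.47. These 5 values are across spots, which are not independent replicates, and carry no p. With each printing position centred, r was 0.14, 0.36, 0.52, 0.47 and 0.45. Arrays of the same number, taken 1 replicate at a time, gave a lower mean r at all times but 30 min, with 0.24 ± 0.09 (SD, n = 3) at 30 min, 0.29 ± 0.22 (SD, n = 3) at 60 min, 0.42 ± 0.10 (SD, n = 3) at 120 min, 0.38 ± 0.23 (SD, n = 3) at 180 min and 0.39 ± 0.11 (SD, n = 3) at 240 min. Arrays of different numbers gave means of 0.01, 0.12, 0.33, 0.22 and 0.18 in the same order. Without replicate 2, r across spots was lower at all times, at 0.0966, 0.191, 0.411, 0.305 and 0.315 in the same order. Without replicate 3 it was 0.241 at 30 min. Few spots could be shown to differ between the assays. The interaction test passed 2 of 4805 spots (limma), with 67 under an unadjusted p of 0.05, and 12 with the replicate block. The 2 became 0 without replicate 2 or 3.

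The authors' deposited table was used for levels, since normalised arrays cannot show a change common to all spots. Over 4468 spots with a value at every time, the mean mRNA abundance in the authors' deposited table was 0.951, 0.982, 0.668, 0.614 and 0.562 times its 0 min value at 30, 60, 120, 180 and 240 min. The mean synthesis rate was 1.04, 0.970, 0.824, 0.610 and 0.584 times its 0 min value. At 240 min 87.8% of the spots had a lower mRNA abundance than at 0 min and 96.0% a lower synthesis rate in the authors' deposited table. Multiplied by the authors' volume factors, the mean synthesis rate was 0.964 of its 0 min value at 120 min, 0.879 at 180 min and 0.964 at 240 min. The mean mRNA abundance multiplied in the same way was 0.782, 0.884 and 0.927, and the sources used here do not say whether volume entered that measure. The medians over spots of the ratio to 0 min were higher than these means for mRNA abundance. In the authors' deposited table its median was 1.04 at 30 min and 1.03 at 60 min, and with the volume factors 0.883, 0.966 and 1.07 at 120, 180 and 240 min. The medians of the synthesis rate with the volume factors were 0.940, 0.855 and 0.942. Whether mRNA abundance with the volume factor lay below 0 min at 240 min thus depended on the average taken. These are the authors' averages, with no replicate values behind them here, so the differences were not tested. Total unnormalised intensity on the nascent arrays rose from 540340, 1091300 and 633800 at 0 min to 1044500, 1848600 and 1768100 at 240 min (replicates 1, 2 and 3). On the mRNA arrays it went from 521650, 963620 and 1008500 to 487880, 1661000 and 724550. The scaling between such totals and the authors' values is not given, so the falls above rest on that scaling.

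**Figure D4:**
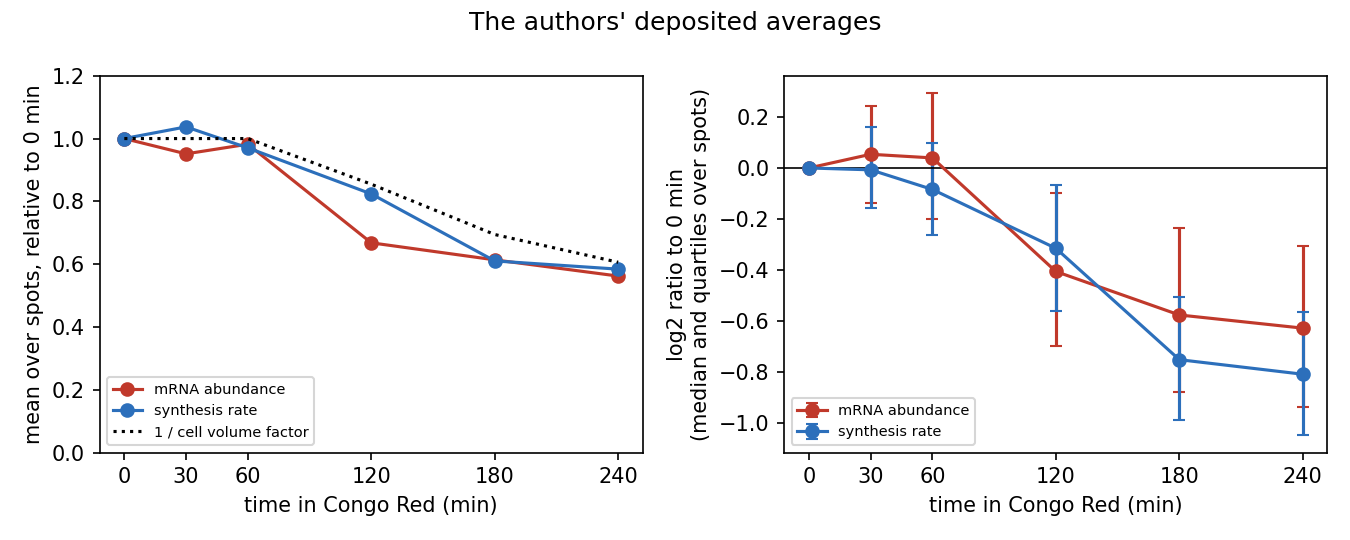
The authors' deposited averages over 4468 spots against time in Congo Red (min). The left panel shows the mean mRNA abundance and the mean synthesis rate relative to 0 min, with 1 divided by the authors' cell volume factor as a dotted line; at 240 min the means were 0.562 and 0.584. The right panel shows the log2 ratio to 0 min, as the median over spots with bars from the lower to the upper quartile; at 240 min the medians were -0.63 and -0.81.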

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

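All the tests over other groupings of the arrays were made after the results had been seen. With 3 arrays against 3 there are only 10 splits, so no share under 0.05 can be reached, and for these comparisons the real count and the highest other count are given.

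The response differed between 240 and 30 min at 5 spots in mRNA abundance and at 13 spots in nascent transcription, as tested directly between the times. For these comparisons 1 of 10 splits gave as many calls in each assay, the real one, and the highest other count was 0 in both. The changes in mRNA and in nascent transcription differed from each other at 2 spots by the interaction test. Of 100 assignments of the arrays to times, the real one included, 31 gave at least 2 spots, and the highest other count was 199, so chance cannot be excluded for these 2 spots. Those assignments ignored the replicate number. With the block the real count was 12. Among 100 assignments within each number of each assay, the real one included, 1 reached it and the highest other count was 4. Those assignments removed every time effect from both assays, and not only a difference between the assays. This share therefore cannot exclude chance for such a difference. The numbers also did not pair the nascent arrays by the criterion used, which limits the blocked count further.

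For mRNA at 60, 120, 180 and 240 min the real splits gave 5, 34, 86 and 81 calls, the highest other counts were 0, 0, 1 and 0, and 1 of 10 splits reached the real count each time. At 30 min the real count was 0, which all 10 splits reached, and the highest other count was 1. Of the 10 splits of 6 arrays, 4 part all 3 pairs of same-numbered arrays, the real one among them. With the replicate block the real splits gave 11, 99, 320, 670 and 639 calls in order of time and the highest other among those 4 gave 0, 1, 0, 1 and 0. For mRNA at any time, 4 of 100 assignments of the 18 arrays gave 27 or more calls. These assignments ignored the replicate number, which paired the mRNA arrays, so this share cannot exclude chance. The highest other count was 509. That count is several times the real one and points to a structure of the arrays other than time. With the block the real count was 298 and the highest other 166.

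For nascent transcription at 30, 60, 120 and 180 min the real counts were 1, 2, 47 and 65, the highest other counts 0, 0, 0 and 1, and 1 of 10 splits reached the real count. At 240 min 2 of 10 splits reached the real count of 41. The other set replicates 1 and 2 at 0 min with replicate 1 at 240 min against the other arrays and gave 255 calls, and 347 against a real 88 after printing positions were centred. Among the 4 splits that part all same-numbered pairs the highest other count was 0. With the block, which is only an alternative for the nascent arrays, the real count was 148 and the highest other among those 4 was 0. A count as large as 255 points to a structure of the arrays, and without replicate 1 at 240 min 146 spots were called at 240 min. For nascent transcription at any time 2 of 100 assignments gave 33 or more calls, with a highest other count of 98. These assignments too ignored the replicate number. With the block the real count was 78 and the highest other 201, so no conclusion on chance is drawn here.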

How the results depend on the processing

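Centring by printing position, leaving out position 3, leaving out the spots blank in the authors' table taking its ratios less their median and leaving out the 0 min arrays were chosen after the data had been seen; the other alternatives were fixed before. When only the 6 arrays compared were fitted, 9 of the 10 counts at single times fell, to 13 or fewer. The cause of the changes below was not tested, except that this fit rests on fewer arrays.

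With the replicate number as a block, mRNA counts at 30, 60, 120, 180 and 240 min, late against early and at any time were 11, 99, 320, 670, 639, 77 and 298. Nascent counts in the same order from 60 min on were 6, 169, 141, 148, 66 and 78, and the interaction passed 12. The nascent calls with the block split into 1 rise and 0 falls at 30 min, 6 and 0 at 60 min, 120 and 49 at 120 min, 120 and 21 at 180 min, 110 and 38 at 240 min, and 43 and 23 late against early. Nascent arrays of the same number had a median r of 0.314 over 45 pairs. The median for different numbers was -0.167, and a value below 0 there follows from taking deviations from the group mean. Same-numbered pairs ranged from -0.232 to 0.652 and 13 lay at or below 0.1. The criterion for pairing was therefore not met and the block is only an alternative there. With centring and the block together the mRNA counts were 12, 122, 365, 699, 681, 98 and 368, the nascent ones 6, 202, 162, 226, 110 and 98, and the interaction passed 13. Centring alone gave 3 for mRNA late against early, and 88 for nascent transcription at 240 min and 53 at any time.

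Scaling to a common median gave 11 mRNA spots at 60 min, 127 at 240 min, 3 late against early and 42 at any time. Cyclic loess gave 14, 53 and 130 at 60, 120 and 180 min, 45 at any time, and 1 nascent spot at 60 min. Without the dimmest 20% of spots, mRNA counts were 14 at 60 min and 8 late against early, nascent ones 85 at 120 min, and r between the assays was 0.243 at 30 min, 0.694 at 120 min and 0.591 at 240 min. A trended and robust prior gave 14 mRNA spots at 60 min and 72 nascent spots at 120 min. With only the 6 arrays compared, mRNA counts at 60, 120, 180 and 240 min were 0, 0, 0 and 1, and nascent counts from 30 min on were 0, 0, 13, 12 and 0. Without position 3, 13 mRNA spots passed at 60 min. Without the blank spots, 10 passed at 60 min and 41 at any time.

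Late against early, 2 mRNA spots and 6 nascent spots passed with the 0 min arrays left out. Leaving out each array in turn, mRNA counts ranged from 0 to 1 at 30 min, 2 to 8 at 60 min, 16 to 28 at 120 min, 37 to 89 at 180 min, 31 to 75 at 240 min, 2 to 5 late against early and 16 to 35 at any time. Nascent counts ranged from 1 to 2 at 30 and at 60 min, 18 to 64 at 120 min, 21 to 62 at 180 min, 12 to 146 at 240 min, 4 to 43 late against early and 11 to 73 at any time. Without each replicate number the interaction passed 0 to 3 spots and r ranged from 0.0966 to 0.241 at 30 min, 0.191 to 0.392 at 60 min, 0.411 to 0.543 at 120 min, 0.305 to 0.544 at 180 min and 0.315 to 0.472 at 240 min.

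The nascent change at 240 min, which did not pass the test for these spots in the report's fit, turned direction in the authors' table for R7 - C16 : 1 (-0.10), R14 - C17 : 8 (-0.75) and R11 - C5 : 12 (-0.92). The synthesis rate there is per cell volume and fell at most spots, while the report's changes are relative to the typical spot. Less the median over spots, an alternative added after the data had been seen, the authors' ratios were 0.71, 0.05 and -0.11, so only that of R11 - C5 : 12 differed in direction, and by this small value. For R14 - C17 : 8 it also ranged from -0.19 to 0.23 when arrays were left out. The planned tests of gene lists, with an estimated correlation, fry and every other alternative to them, were not run because spots could not be paired with genes. Dim signal limits the named spots, all below percentile 20 of the mRNA signal.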

Other observations

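All the tests in this part were chosen after the results had been seen. Spots with a bright mRNA signal tended to lose mRNA signal relative to dim ones late in the course. On arrays scaled to a common median, the median change of the 20% of spots brightest in mRNA minus that of the 20% dimmest was -0.38 ± 0.21 (SD, n = 3) at 240 min in log2 mRNA. It was negative in all 3 replicates (-0.61, -0.20 and -0.33), too few for an exact sign test to pass 0.05. At 60 min it was -0.11 ± 0.09 (SD, n = 3). The same difference in nascent transcription was -0.08 ± 0.09 (SD, n = 3) at 240 min, so it was within the spread between replicates there. In the authors' deposited table the median mRNA ratio at 240 min went from -0.43 in the lowest of 5 equal abundance classes to -0.77 in the highest, while that of the synthesis rate stayed between -0.83 and -0.76 in all 5. Classes were set by the mean mRNA signal over all times, with no background subtracted on the arrays. Brightness of a spot there is not a measured scale of abundance between transcripts. Whether the assays differ in this was not tested.

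The mRNA changes at 180 and 240 min correlated across spots with the nascent change at 120 min about as closely as with the nascent change of their own time. For mRNA at 240 min r was 0.49 with nascent transcription at 120 min and 0.46 with that at 240 min. For mRNA at 60 min r was 0.46 with nascent transcription at 120 min and 0.41 with that at 60 min. Nascent transcription at 120 min gave the highest r with mRNA of every time, so this ranking can neither show nor exclude a delay. In the authors' deposited table the median ratio of synthesis rate to mRNA abundance was 0.0513 at 0 min, 0.0529 at 120 min and 0.0439 at 240 min. The synthesis rate is per cell volume, and the sources used here do not say whether mRNA abundance is. The direction of this ratio from 120 min on therefore cannot be read.

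The spots at printing position 3 drifted from array to array, alike in both assays: on the mRNA arrays their median deviation in replicates 1, 2 and 3 was 0.37, 0.55 and 0.13 at 0 min and -0.76, 0.53 and 0.33 at 240 min, and on the nascent arrays 0.45, 0.36 and 0.20, then -0.38, 0.29 and 0.27. Over the 18 pairs of arrays with the same time and number r was 0.893 (permutation p = 1e-05, the smallest the permutations can give; adjusted over 16 positions 0.00016), rho was 0.860 (permutation p = 1e-05), and r was 0.937 without the 2 farthest pairs. Up to 120 min the level fell at each step in every replicate of both assays. At 120 min it stood at -0.08, -0.18 and -0.52 on the mRNA arrays and at -0.01, -0.39 and -0.68 on the nascent arrays. Over that span the drift cannot be told apart from time in Congo Red. A response to time alone over the whole course is argued against, since 6 of the 12 arrays at 180 and 240 min lay above the lowest 0 min array of their assay. A shared culture stays open: same-numbered arrays of the 2 assays had a median r of 0.0040 over all spots after centring and 6 of 18 mRNA arrays were closest to the nascent array of their number, while the mean r of their changes from 0 min, 0.320, was the highest of 6 matchings of the numbers (next 0.221), which cannot give a p under 0.167. Arrays shared between the assays or used in sequence may account for the drift at position 3. Once each time's mean was taken off, r was 0.854 (exact permutation p = 0.00135, adjusted 0.0072). Positions 6 and 9 gave -0.801 and -0.847 in the same way, which leaves this open. In both assays replicate 3 was the lowest at each time up to 120 min. The permutations took the arrays or the times as independent, so their p-values may be too small.

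There were 175 spots that had signal on all 36 arrays and no value in the authors' table. They lay at a median percentile of 88.5 among the other spots on the nascent arrays and of 33.2 on the mRNA arrays, so a filter on dim signal is argued against as the whole cause. Transcripts poorly primed by oligo-dT are a candidate explanation, and 47.4% of these spots lay above the 90th percentile of nascent over mRNA signal among the others, where 10% of the others lie by construction, so it can account for a part at most and stays open. Of the 175, 43 lay at printing position 13. No biological explanation was tested.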
